A study of Mus musculus with 8 samples.

How the data were processed

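Gene expression was measured on 8 Affymetrix expression arrays, each hybridised with biotin-labelled total RNA of the mouse embryonic stem (ES) cell line E14Tg2a, labelled by in vitro transcription, per the labels' protocols. The labels put 2 arrays in each of 4 groups: a control siRNA at 96 h, Tet1 siRNA 1 at 96 h, Tet1 siRNA 2 at 96 h and Tet1 siRNA 1 at 48 h. No control at 48 h was analysed here. Nothing in the labels says whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Array batches and hybridisation or scan dates are not given in the sources used here.

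The deposited values are RMA expression values on the log2 scale, 1 value per probe set and array. RMA, which corrects background, normalizes the arrays to one distribution and summarises the probes of a probe set, is named in the submitters' processing notes without a version. The log2 scale was read from the values, which lay between 2.60 and 15.3 on every array, with medians from 6.68 to 6.72. All 8 columns were matched to samples by their names, and 0 columns belonged to other samples. Because RMA normalizes arrays to one distribution, differences in total RNA per cell are not visible in these values. Whether all 8 arrays were normalized in one run was not tested here. The number of arrays limits the precision. Scanner signal and background values were not used here, so no detection limit could be set for dim genes. The probe sets for trp, a bacterial transcript taken here as not added, gave the level of an absent transcript.

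Of 16556 probe sets, 64 were Affymetrix control probe sets and were left out of all gene tests. Gene symbols came from the platform's probe annotation, updated through the Entrez gene ID, which changed 0 symbols. It paired 15270 probe sets with exactly 1 symbol and 0 with several. The other 1222 probe sets were not listed there and stayed unnamed, and they entered no gene count. Of the listed probe sets, 15250 have their Entrez gene ID as their number. The unlisted ones were not named through theirs, so whether one of them measures Tet1 was not looked up. Where a gene had more than 1 probe set (3 genes), the probe set with the highest mean over all arrays was used, which left 15267 genes. No genome build was used, and no coordinates are given. The annotation names no probe set for Tet1, so the level of the siRNAs' target was not analysed here and the knockdown labels were not checked against it. The same holds for T (brachyury), which was also to be named.

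Differential expression was tested with limma 3.58.1 in R 4.3.3 on the log2 values. A group-means model was fitted to all 8 arrays, so that the 4 groups shared an estimate of the spread (4 residual degrees of freedom plus 4.13 prior degrees of freedom from eBayes, with trend and robust options off). Adjusted p-values are two-sided limma p-values with Benjamini-Hochberg adjustment over 15267 genes in each comparison, and a gene was called at an adjusted p below 0.05. In total 6 comparisons were made, 3 of them against the control at 96 h: siRNA 1, siRNA 2, and the mean of both siRNAs with equal weight, which was the main comparison. The others set siRNA 1 against siRNA 2 at 96 h, siRNA 1 at 96 h against 48 h, and siRNA 1 at 48 h against the control at 96 h. No replicate block was used in the main model, since the labels do not say that a replicate number marks a shared culture or day. Values after ± are standard errors of the fitted difference unless an SD is named.

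A total of 25 gene lists was written from general knowledge before the data were examined, as were the rule for naming genes, the model and most of the other settings tried. Each list was tested with camera (limma) at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 25 lists within a comparison. Camera compares a list's genes with all other genes. It was run beside camera with an estimated correlation, and beside fry, which tests whether a list's genes move, on balance, one way and makes no comparison with other genes. With an estimated correlation, 0 lists were called in every comparison; the adjusted p is given at each called list. Counts of members refer to adjustment over all genes unless they are said to be adjusted over the list alone.

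The genes named are those set by a fixed rule. In each comparison these are the 8 genes with the largest rise and the 8 with the largest fall (10 and 10 in the main comparison) among called genes whose arrays do not overlap between the compared groups. To these come, per list, up to 4 called members with the smallest adjusted p (the 2 with the smallest p where fewer than 2 were called), of which the text takes the first in order where space is short. A fixed panel was always named in the main comparison: Tet2, Tet3, Pou5f1, Nanog, Sox2, Klf4, Esrrb, Stat3, Socs3, Lefty1, Cdx2, Gata6 and Pax6. Predicted genes and clones without an established symbol were passed over. A list of 24 lung genes and lists of 6 other tissues were written only after lung transcripts had been seen among the largest differences between the 48 h and 96 h arrays.

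The 2 siRNAs share the control arrays, so chance values for the agreement of their fold changes came from 1000 simulated pairs of unchanged groups against a shared control, with the fitted spread, and 100 such pairs were refitted to count shared calls. Splitting the 2 control arrays would leave 1 on each side, so the controls were not split. The scripts were tested on simulated data of 15267 genes, of which 200 changed. In the main comparison 93% of changes of 0.5 on the log2 scale and 100% of changes of 1 were recovered, and 4.93% of the called genes were unchanged ones. For siRNA 1 against the control 72% and 100% were recovered, and for siRNA 1 against siRNA 2 it was 60% and 99%. In 20 simulated data sets without changes, with 25 lists tested in each, camera made 1 call in all. With the naive pluripotency list shifted by -0.3, camera called that list and 2 others.

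The alternatives tried were eBayes with an intensity trend or robust, array weights, quantile normalization and median centring of the deposited values, filters on dim genes (below the median or the 25th percentile of the gene means), the mean over probe sets of a gene, all probe sets as separate rows, fitting only the arrays compared, a stricter adjusted p of 0.01, a fold minimum of 1.5, a replicate block, and leaving out each array. A pseudocount setting was not run because the values were already on the log2 scale, and robust eBayes was not run for camera, which does not use it. Added after the data were seen were fits without the 48 h arrays and fits that also carry the mean of the lung genes as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.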

Results

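Expression was profiled in E14Tg2a cells, a mouse embryonic stem (ES) cell line, after transfection with small interfering RNAs (siRNAs). Tet1 encodes a dioxygenase that converts methylated cytosine in DNA to its hydroxymethylated form. Different siRNA duplexes against Tet1, here siRNA 1 and siRNA 2, were compared with a control duplex directed at firefly luciferase, which mouse cells lack. The 8 arrays fell into 4 groups of 2: control at 96 h, siRNA 1 at 96 h, siRNA 2 at 96 h and siRNA 1 at 48 h. The series title frames the question as whether loss of Tet1 affects signalling by leukaemia inhibitory factor (LIF) through Stat3 and the identity of ES cells. Each array gave 16556 RMA log2 values with a median between 6.68 and 6.72. Arrays of the same group correlated across genes with Pearson's r from 0.997 to 0.998, and arrays of different groups with r from 0.983 to 0.997. The first principal component, with 53.1% of the variance, set the 48 h arrays (32.9 and 35.4) apart from the 6 arrays of 96 h. On it the control arrays (-0.89 and -0.78) lay between the 48 h arrays and the siRNA arrays of 96 h (-18.4 to -14.3). The second component, with 28.1%, set the control arrays apart from the siRNA arrays. The level of Tet1 itself was not analysed here, because the probe annotation names no probe set for it, so the labels were not checked against the target.

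The main comparison asked what changed with both Tet1 siRNAs at 96 h. Markers of naive pluripotency, the ground state of mouse ES cells, fell together. Of 20 measured members 17 fell, 0 rose and 3 did not pass, with a median log2 fold change of -0.78. Tbx3 fell by 1.36 ± 0.061, Tfcp2l1 by 1.28 ± 0.072 and Jam2 by 1.34 ± 0.077 on the log2 scale (SE; 4 siRNA arrays against 2 control arrays). Esrrb, a nuclear receptor that sustains self-renewal, fell by 1.11 ± 0.068, which is 2.16-fold, with an adjusted p of 3.9e-05 (limma, Benjamini-Hochberg). Klf4 fell by 0.92 ± 0.069 and Tet2, a relative of Tet1, by 0.69 ± 0.078. Adjusted over the list alone, 19 members were lower. Camera called the list (adjusted p = 1.3e-13), and the adjusted p was 0.0978 with an estimated correlation.

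Genes of the formative and primed epiblast, the state that follows naive pluripotency in the embryo, rose. Of 19 measured members 12 rose, 1 fell and 6 did not pass, and 13 were higher and 1 lower adjusted over the list alone. The median log2 fold change was 0.42. Fgf5, a growth factor gene of the epiblast, rose by 2.04 ± 0.13, Car4 by 1.94 ± 0.076, Sall2 by 1.59 ± 0.077 and Dusp6, a feedback inhibitor of ERK signalling, by 1.03 ± 0.064. Camera called the list (adjusted p = 3.7e-08), with an adjusted p of 0.0978 with an estimated correlation.

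**Figure D1:**
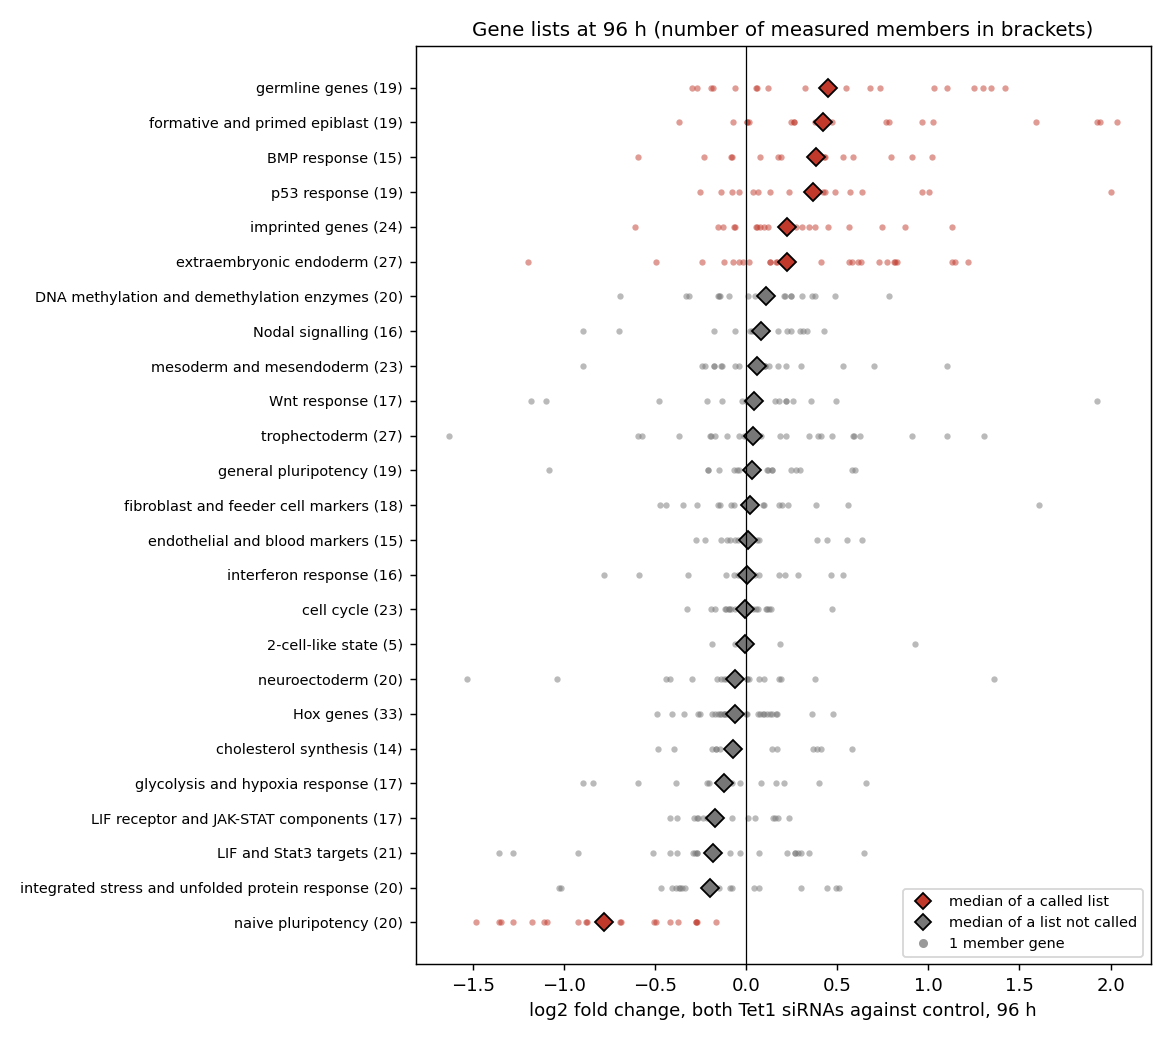
Log2 fold change of both Tet1 siRNAs against the control at 96 h (horizontal axis) for the members of each gene list (vertical axis). Circles are genes and diamonds are list medians (red where camera called the list), and the naive pluripotency list lies at the lower end with a median of -0.78, and the germline and epiblast lists at the upper end with medians of 0.45 and 0.42.

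Markers of pluripotency in general did not move together. Of 19 members 4 rose, 2 fell and 13 did not pass, the median was 0.034 and camera made no call (adjusted p = 0.383). Adjusted over the list alone, 4 were higher and 3 lower. Nanog, a homeodomain factor of the pluripotency network, fell by 1.08 ± 0.083 (2.11-fold, adjusted p = 9.4e-05), while Epcam rose by 0.60 ± 0.080, Utf1 by 0.58 ± 0.079 and Tdgf1 by 0.30 ± 0.070. The log2 fold change of Pou5f1, the gene of Oct4, was -0.15 ± 0.074 (adjusted p = 0.194). Sox2 fell by 0.21 ± 0.061 with an adjusted p of 0.0400, and its call was lost when any single 96 h array was left out (adjusted p 0.158 and 0.152 without control replicate 1 or 2, 0.0831 and 0.0824 without siRNA 1 replicate 1 or 2, 0.0628 and 0.0913 without siRNA 2 replicate 1 or 2) and when either 48 h array was left out (0.0501 each). Tdgf1 lost its call without control replicate 1 (0.0959) or 2 (0.0687).

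The LIF pathway was looked at as 2 lists. Of 17 measured components, receptors, kinases, Stat factors and their inhibitors, 4 fell, 1 rose and 12 did not pass, with a median of -0.17 and no call by camera (adjusted p = 0.227). Adjusted over the list alone, 5 were lower and 1 higher. Stat3, the transcription factor that LIF activates in these cells, fell by 0.27 ± 0.070 (1.20-fold, adjusted p = 0.0254), Pias3, an inhibitor of Stat3, by 0.42 ± 0.075 and the kinase gene Tyk2 by 0.29 ± 0.065, and Jak1 rose by 0.23 ± 0.067. Of 21 measured targets of LIF and Stat3, 9 fell, 6 rose and 6 did not pass, with a median of -0.18. Adjusted over the list alone, 10 were lower and 7 higher, and camera made no call (adjusted p = 0.227). Fry, which makes no comparison with other genes, called both lists lower (adjusted p = 0.0309 for the components and 6.3e-05 for the targets). It was not particular to them, as it called 15 of 25 lists in this comparison, where camera called 7. Socs3, the feedback inhibitor that Stat3 induces, fell by 0.38 ± 0.065 (adjusted p = 0.0043). The list shares 5 genes with the naive list, and 4 of these fell, Tbx3, Tfcp2l1, Klf4 and Gbx2. Of the other 16 targets 5 fell and 6 rose, with a median of 0.019. The Stat3 call was lost without control replicate 1 (adjusted p = 0.169), control replicate 2 (0.0531), siRNA 1 replicate 1 (0.0642) or siRNA 2 replicate 2 (0.0649). Pias3 lost its call without control replicate 2 (0.0516), as did Tyk2 (0.106), and Jak1 lost it without control replicate 1 (0.125) or 2 (0.164), siRNA 1 replicate 2 (0.0915), siRNA 2 replicate 1 (0.0735) or 2 (0.0753), or either 48 h array (0.0562 each).

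**Figure D2:**
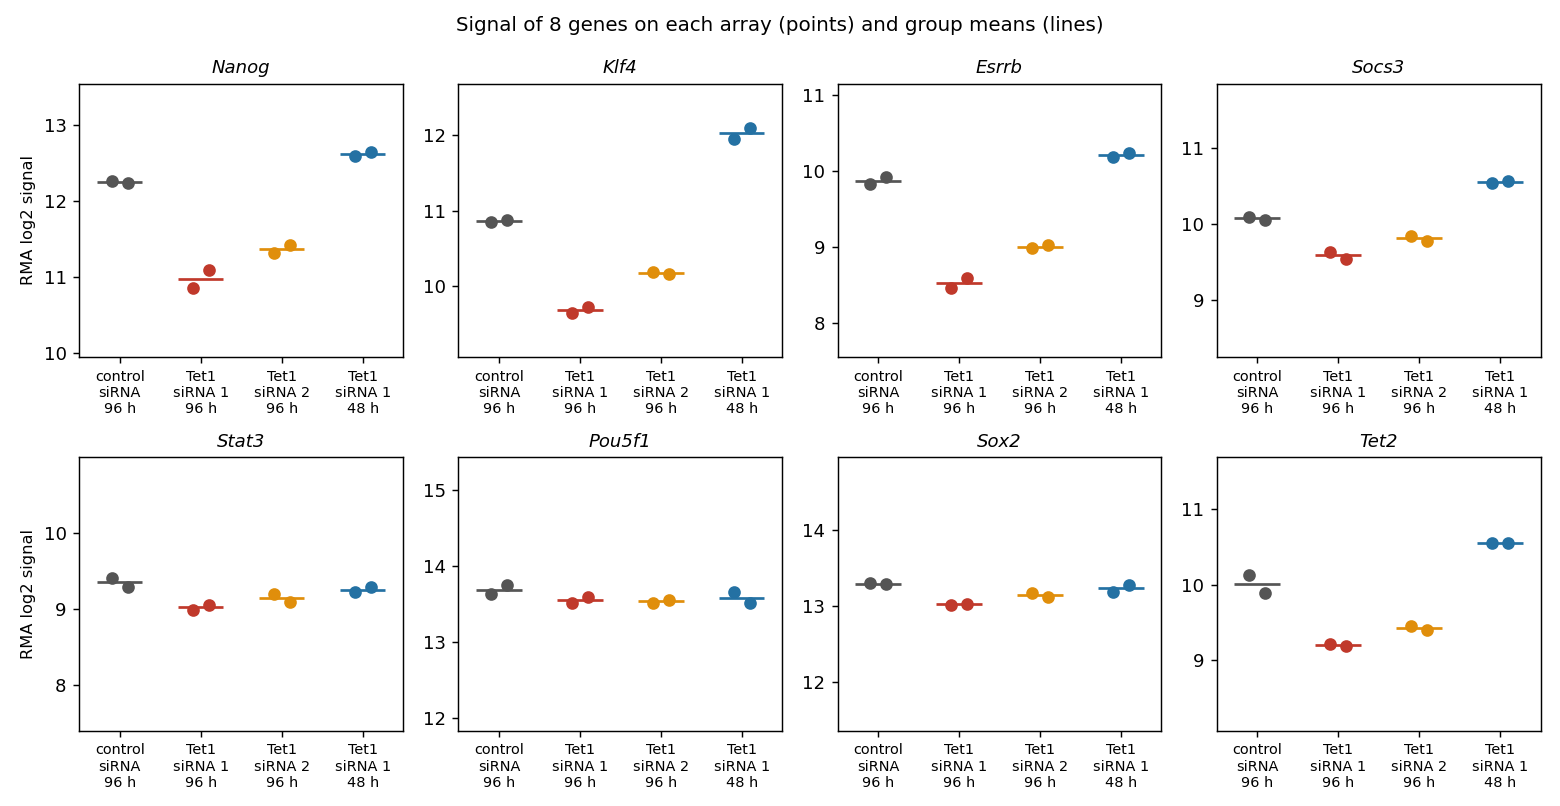
RMA log2 signal (vertical axis, each panel spanning the same number of log2 units) of 8 genes on each array, grouped by siRNA and time (horizontal axis). Points are arrays and lines are group means, and Nanog, Klf4, Esrrb, Socs3 and Tet2 lie below the controls in all 4 siRNA arrays of 96 h and above the control mean in both arrays of 48 h, and the Klf4 means run from 9.69 with siRNA 1 at 96 h to 12.02 at 48 h.

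Among lists of early lineages, the extraembryonic endoderm list was called. Of its 27 members 13 rose, 2 fell and 12 did not pass (13 and 3 adjusted over the list alone), with a median of 0.22 and a camera adjusted p of 0.000234. The adjusted p was 0.125 with an estimated correlation. The basement membrane genes Col4a2 and Lamb1 rose by 0.81 ± 0.075 and 0.77 ± 0.081 and the endocytic receptor gene Lrp2 by 1.14 ± 0.12, whereas Apoe fell by 1.20 ± 0.091. The log2 fold change of Gata6, a master regulator of this lineage, was 0.17 ± 0.096 (adjusted p = 0.235).

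The trophectoderm list was not called (9 rose, 4 fell, 14 did not pass, 9 and 5 adjusted over the list alone, median 0.039, camera adjusted p = 0.227). Krt18, a keratin of simple epithelia, rose by 1.31 ± 0.080 and Eomes by 1.10 ± 0.080, and Lgals3 and the glucose transporter gene Slc2a3 fell by 1.63 ± 0.068 and 0.57 ± 0.063. The log2 fold change of Cdx2, the key trophectoderm factor, was 0.039 ± 0.087 (adjusted p = 0.786). The mesoderm and mesendoderm list (3 rose, 1 fell, 19 did not pass, the same counts adjusted over the list alone, median 0.059, camera adjusted p = 0.383) held rises of Eomes and of Msx2 (0.53 ± 0.074) and a fall of Lefty2 by 0.89 ± 0.13. In the neuroectoderm list (2 rose, 4 fell, 14 did not pass, the same adjusted over the list alone, median -0.060, camera adjusted p = 0.472) the neuronal tubulin gene Tubb3 fell by 1.53 ± 0.11, Ncam1 by 1.04 ± 0.13 and Pax6 by 0.44 ± 0.078, and Zic1 rose by 1.36 ± 0.15. Pax6 was dim, with means of 5.26 in the controls, 4.83 with siRNA 1 and 4.80 with siRNA 2. Of 33 Hox genes, Hoxd13 rose by 0.36 ± 0.096, Hoxc13 fell by 0.49 ± 0.15 and 31 did not pass, with 0 called adjusted over the list alone (median -0.061, camera adjusted p = 0.545). Without control replicate 2 the adjusted p was 0.187 for Hoxd13 and 0.105 for Hoxc13, and both calls were also lost without siRNA 1 replicate 1 (0.0609 and 0.0927) or 2 (0.0628 and 0.0923). The Hoxd13 call was lost without siRNA 2 replicate 1 (0.0635), and the Hoxc13 call without siRNA 2 replicate 2 (0.0915) or control replicate 1 (0.186).

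A further 4 lists were called, all higher. In the p53 response list 11 of 19 members rose, 0 fell and 8 did not pass, the same adjusted over the list alone (median 0.37, camera adjusted p = 1.6e-05). The adjusted p was 0.0978 with an estimated correlation. Pmaip1, the gene of the apoptosis factor Noxa, rose by 2.00 ± 0.066, Plk2 by 1.01 ± 0.061, Perp by 0.97 ± 0.063 and the cell cycle inhibitor gene Cdkn1a by 0.63 ± 0.071. In the germline list 9 of 19 members rose, 1 fell and 9 did not pass, or 10 and 2 adjusted over the list alone (median 0.45, camera adjusted p = 0.000275). The adjusted p was 0.121 with an estimated correlation and 0.0526 without the genes below the median gene mean. The RNA helicase gene Ddx4 rose by 1.10 ± 0.058, Mael by 1.25 ± 0.087, Taf7l by 1.42 ± 0.12 and the synaptonemal complex gene Sycp1 by 1.34 ± 0.12. Imprinted genes, which are expressed from the allele of one parent, rose in 8 of 24 cases, with 1 fall and 15 not passing, or 10 and 1 adjusted over the list alone (median 0.225, camera adjusted p = 0.0011). The adjusted p was 0.0978 with an estimated correlation and 0.0526 without the genes below the median gene mean. Ndn rose by 0.74 ± 0.077, Sgce by 0.87 ± 0.096 and Peg10 by 1.13 ± 0.13, and Peg3 fell by 0.61 ± 0.085. In the BMP response list 8 of 15 members rose, 2 fell and 5 did not pass, the same adjusted over the list alone (median 0.38, camera adjusted p = 0.0012). The adjusted p was 0.125 with an estimated correlation. Id1, Id2 and Id3, inhibitors of differentiation that BMP signals induce, rose by 0.80 ± 0.063, 0.59 ± 0.069 and 1.02 ± 0.083, and Dusp9 by 0.91 ± 0.065.

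Other signalling and enzyme lists held changes in both directions and were not called. In the Nodal list (5 rose, 2 fell, 9 did not pass, 7 and 2 adjusted over the list alone, median 0.083, camera adjusted p = 0.227) the Nodal antagonist genes Lefty1 and Lefty2 fell, Lefty1 by 0.70 ± 0.14, and the inhibitory Smad gene Smad7 rose by 0.43 ± 0.065. Lefty1 lost its call without control replicate 2 (adjusted p = 0.0543). In the Wnt list (5 rose, 3 fell, 9 did not pass, 5 and 3 adjusted over the list alone, median 0.041, camera adjusted p = 0.430) Lef1 rose by 1.93 ± 0.13, and the secreted Wnt inhibitor genes Sfrp1 and Notum fell by 1.18 ± 0.065 and 1.10 ± 0.076. Among enzymes of DNA methylation and demethylation (7 rose, 3 fell, 10 did not pass, 8 and 3 adjusted over the list alone, median 0.11, camera adjusted p = 0.227) the methyltransferase gene Dnmt3b rose by 0.79 ± 0.061, Gadd45a by 0.49 ± 0.072 and Uhrf2 by 0.36 ± 0.059, and Tet2 fell. The log2 fold change of Tet3 was -0.14 ± 0.096 (adjusted p = 0.327).

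Stress and metabolic lists were not called either. The integrated stress and unfolded protein response list had 10 falls, 3 rises and 7 members that did not pass (10 and 4 adjusted over the list alone, median -0.20, camera adjusted p = 0.0786). Atf4, its central transcription factor gene, fell by 0.47 ± 0.072, Chac1 by 1.01 ± 0.13 and Nupr1 by 1.03 ± 0.13, and Ddit4 rose by 0.49 ± 0.060. This list passed without control replicate 1 (adjusted p = 0.0240), with an intensity trend (0.0411) and with quantile normalization (0.0443). The glycolysis and hypoxia list (2 rose, 3 fell, 12 did not pass, 4 and 6 adjusted over the list alone, median -0.12, camera adjusted p = 0.383) held falls of the phosphofructokinase gene Pfkp by 0.89 ± 0.092 and of Ankrd37 by 0.84 ± 0.089. In the cholesterol synthesis list (4 rose, 2 fell, 8 did not pass, 4 and 3 adjusted over the list alone, median -0.069, mean 0.028, camera adjusted p = 0.719) Sqle rose by 0.58 ± 0.080 and Cyp51 by 0.41 ± 0.063. The interferon response list (3 rose, 2 fell, 11 did not pass, the same adjusted over the list alone, median 0.0072, mean -0.0080, camera adjusted p = 0.545) held a fall of Irf9 by 0.78 ± 0.091 and a rise of Bst2 by 0.53 ± 0.069. Of 23 cell cycle genes, Ccne2 rose by 0.47 ± 0.065, Ccnd3 fell by 0.32 ± 0.086 and 21 did not pass (1 and 0 adjusted over the list alone, median -0.0052, camera adjusted p = 0.946), and Ccnd3 lost its call without control replicate 1 (adjusted p = 0.134), control replicate 2 (0.0832) or siRNA 2 replicate 1 (0.0640). Of 5 measured genes of the state that resembles the 2-cell embryo, Arg2 rose by 0.93 ± 0.13 and 4 did not pass, the same adjusted over the list alone (median -0.0053, mean 0.17, camera adjusted p = 0.383).

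Over all genes, 3700 of 15267 (24.2%) were called in the main comparison, 1836 higher and 1864 lower, and 875 of them changed at least 1.5-fold. The largest rises were those of Rasef (6.73-fold, log2 2.75 ± 0.16), the ubiquitin ligase gene Rnf128 (5.60-fold, log2 2.49 ± 0.061), the neurofilament gene Nefm (log2 2.32 ± 0.097), Fndc3c1 (2.17 ± 0.10), Tmem54 (2.14 ± 0.094), the calcitonin receptor gene Calcr (2.09 ± 0.14), Fgf5, Pmaip1, Car4 and Lef1. The largest falls were those of Serpinb6c (4.97-fold, log2 -2.31 ± 0.060), the metal ion transporter gene Slc11a1 (-1.84 ± 0.11), H3c15 (-1.79 ± 0.072), Stmn3 (-1.79 ± 0.083), Pla1a (-1.66 ± 0.091), Lgals3, Patl2 (-1.62 ± 0.10), the keratin gene Krt17 (-1.61 ± 0.14), Accsl (-1.61 ± 0.097) and Ankrd35 (-1.57 ± 0.13). H3c15 is one of several nearly identical histone genes, and its probes may not tell them apart. Rasef, Nefm, Fgf5 and Lef1 were dim in the controls (means 4.71, 4.70, 4.65 and 4.79). The count was 2307 without control replicate 1 and 2218 without control replicate 2, and in fits chosen after the data were seen it was 3321 without the 48 h arrays and 2581 when the mean of the lung genes was also a covariate.

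Markers of other cells were checked in the same comparison. The fibroblast and feeder cell list was not called (3 rose, 1 fell, 14 did not pass, 3 and 2 adjusted over the list alone, median 0.019, camera adjusted p = 0.413), with Tagln, an actin-binding protein of smooth muscle, up by 1.61 ± 0.078 and Col5a1 up by 0.56 ± 0.067. The endothelial and blood list (3 rose, 0 fell, 12 did not pass, the same adjusted over the list alone, median 0.013, camera adjusted p = 0.545) held rises of the receptor gene Tek by 0.64 ± 0.12 and of Tal1 by 0.55 ± 0.11, and Tal1 lost its call without control replicate 2 (adjusted p = 0.0593). All 6 arrays of 96 h carried lung transcripts, controls included. Scgb1a1, the secretoglobin of airway club cells, had a mean signal of 12.47 ± 0.32 (SD, n = 6), and Sftpc, surfactant protein C of alveolar cells, one of 10.30 ± 0.28 (SD, n = 6). The 21 measured lung genes had a median log2 fold change of -0.082 between siRNA and control arrays of 96 h, and 2 were called, Napsa (-1.34, adjusted p = 0.000125) and Bpifa1 (-0.88, adjusted p = 0.0165).

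Taken apart, the siRNAs gave changes of the same kind. With siRNA 1 at 96 h, 3487 genes were called, 1778 higher and 1709 lower, and with siRNA 2 it was 2392, 1223 higher and 1169 lower. The largest rise was that of Rasef with either duplex (log2 2.82 ± 0.18 with siRNA 1 and 2.68 ± 0.18 with siRNA 2), followed by Rnf128 (2.60 ± 0.071 and 2.37 ± 0.071) and Nefm (2.40 ± 0.11 and 2.24 ± 0.11). Tmem54 (2.37 ± 0.11 and 1.91 ± 0.11), Fndc3c1 (2.29 ± 0.12 and 2.04 ± 0.12), Calcr (2.24 ± 0.16 and 1.94 ± 0.16) and Fgf5 (2.15 ± 0.15 and 1.93 ± 0.15) were among the 8 largest for both, Pmaip1 (2.29 ± 0.076) for siRNA 1 and Lef1 (1.90 ± 0.15) for siRNA 2. Serpinb6c fell most, by 2.75 ± 0.069 with siRNA 1 and by 1.88 ± 0.069 with siRNA 2. Stmn3 (-2.17 ± 0.096 and -1.42 ± 0.096), H3c15 (-1.96 ± 0.083 and -1.63 ± 0.083) and Slc11a1 (-1.86 ± 0.12 and -1.83 ± 0.12) were among the largest falls for both, Accsl (-2.01 ± 0.11), Lgals3 (-1.91 ± 0.078), Lrrc34 (-1.84 ± 0.11) and Mras (-1.83 ± 0.11) for siRNA 1, and Krt17 (-1.56 ± 0.16), Pla1a (-1.51 ± 0.11), Patl2 (-1.45 ± 0.12) and Casq2 (-1.36 ± 0.24) for siRNA 2.

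Nanog fell by 1.28 ± 0.096 with siRNA 1 and by 0.88 ± 0.096 with siRNA 2, Klf4 by 1.17 ± 0.079 and 0.68 ± 0.079, Esrrb by 1.35 ± 0.079 and 0.87 ± 0.079, and Tet2 by 0.81 ± 0.090 and 0.58 ± 0.090. Stat3 fell by 0.33 ± 0.080 with siRNA 1 (adjusted p = 0.0211), and its log2 fold change with siRNA 2 was -0.21 ± 0.080 (adjusted p = 0.128). The Stat3 call with siRNA 1 was lost without control replicate 1 (adjusted p = 0.111), siRNA 1 replicate 1 (0.101) or siRNA 1 replicate 2 (0.0635). Camera called the same 7 lists for each siRNA as in the main comparison, and none held with an estimated correlation (lowest adjusted p = 0.0809 for siRNA 1 and 0.0934 for siRNA 2). The median of the naive list was -0.91 with siRNA 1 and -0.65 with siRNA 2, that of the epiblast list 0.47 and 0.38, and that of the p53 list 0.50 and 0.24. The BMP list was no longer called for siRNA 1 without siRNA 1 replicate 1 (adjusted p = 0.0693). The stress response list passed without control replicate 1 (0.0245 for siRNA 1 and 0.0279 for siRNA 2) and, for siRNA 1, without siRNA 1 replicate 2 (0.0495). It also passed with an intensity trend (0.0439 and 0.0488) and, for siRNA 1, with quantile normalization (0.0388). Without the genes below the median gene mean it passed for siRNA 2 (0.0439). That filter ended the calls of the germline list for siRNA 1 (0.0663) and the imprinted list for siRNA 2 (0.0967). Leaving out 1 array moved the count for siRNA 1 by over 1.5 times in 3 cases, to 2226 without control replicate 2, 2313 without siRNA 1 replicate 1 and 1906 without siRNA 1 replicate 2, and for siRNA 2 in 4 cases, to 1432 and 1278 without control replicate 1 or 2 and 1419 and 1160 without siRNA 2 replicate 1 or 2. For siRNA 2 it was 1364 when only the arrays compared were fitted and 1344 with the lung covariate.

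The fold changes of the siRNAs were then set against each other. Across genes, which are not independent replicates, they correlated with Pearson's r of 0.899 and Spearman's rho of 0.829. Both use the same control arrays, and simulated unchanged groups with shared controls gave a mean r of 0.50. The covariance was 0.0886, against a mean of 0.0060 and a maximum of 0.0065 over 1000 simulations. Of the called genes, 1116 were higher with both siRNAs, where independent lists would share 142.4, and 963 were lower with both, where independent lists would share 130.9. None was called in opposite directions (0 genes). In 100 refits of simulated unchanged groups with a shared control, 0 genes were called in both. Part of the excess in these overlaps may still come from the shared controls, which were too few to split. The refits held no changed genes, so they cannot show how much the shared controls add where many genes change. Of the 3700 genes called in the main comparison, 74.2% had the larger change with siRNA 1, and the slope of siRNA 2 on siRNA 1 through the origin was 0.79.

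**Figure D3:**
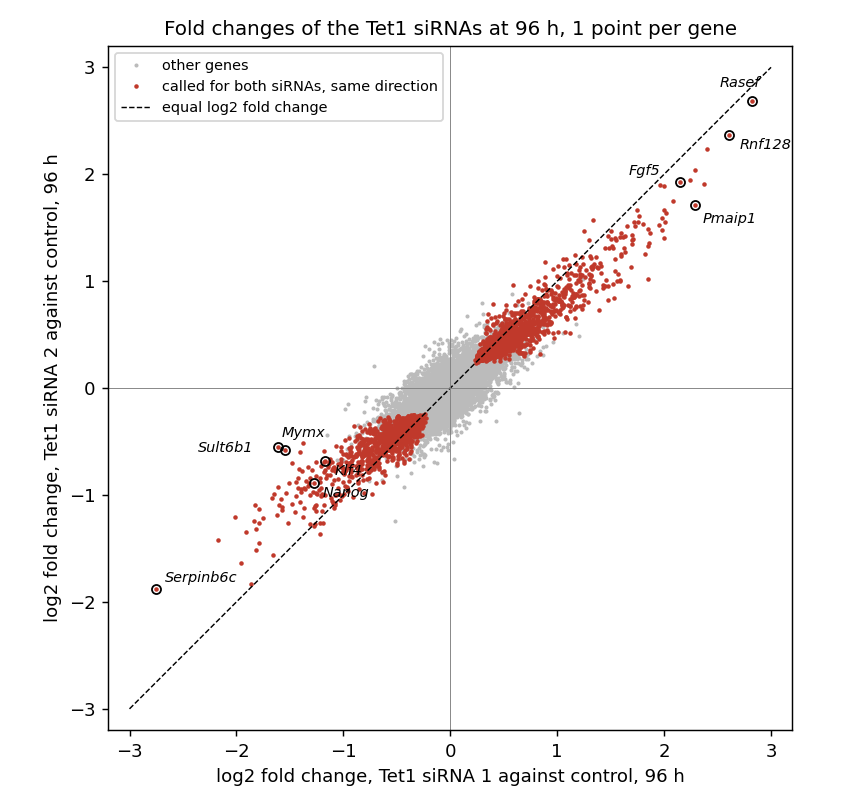
Log2 fold change against the control at 96 h of each gene with Tet1 siRNA 1 (horizontal axis) and with Tet1 siRNA 2 (vertical axis). Red points are the 1116 genes called higher and the 963 called lower with both siRNAs, grey points are all other genes, and the dashed line marks equal change, with Nanog at -1.28 on the horizontal and -0.88 on the vertical axis.

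The direct comparison of siRNA 1 with siRNA 2 at 96 h called 3 genes, all lower with siRNA 1. They were Sult6b1 (log2 difference -1.06 ± 0.098, adjusted p = 0.0205), Mymx, a micropeptide gene of muscle cell fusion (-0.97 ± 0.082, adjusted p = 0.0157), and Serpinb6c (-0.88 ± 0.069, adjusted p = 0.0157). At an unadjusted p below 0.05 there were 1625 genes, where chance would give 763.4. As a group, naive pluripotency genes were lower with siRNA 1 than with siRNA 2, with a median difference of -0.32 (camera adjusted p = 7.7e-12, and adjusted p = 0.153 with an estimated correlation). Of the 20 members 0 passed over all genes and 15 were lower adjusted over the list alone. Klf4 differed by -0.49 ± 0.079 (adjusted p = 0.133) and Prdm14, a repressor that protects the naive state, by -0.78 ± 0.13 (adjusted p = 0.133). Camera also called the p53 list higher with siRNA 1 (median 0.22, adjusted p = 4.0e-07, and adjusted p = 0.0964 with an estimated correlation), with 6 of 19 members higher adjusted over the list alone. Within it Pmaip1 differed by 0.58 ± 0.076 (adjusted p = 0.1004) and Mdm2 by 0.40 ± 0.074 (adjusted p = 0.156). The epiblast list was likewise higher (median 0.11, adjusted p = 0.00038, and adjusted p = 0.330 with an estimated correlation), with 2 of 19 members higher adjusted over the list alone, and differences of 0.52 ± 0.088 for Sall2 (adjusted p = 0.139) and 0.42 ± 0.088 for Pou3f1 (adjusted p = 0.1585). The count was 0 without any one of the siRNA 1 or siRNA 2 arrays, without either 48 h array, or in a fit without both, and 3 without either control array. It was 124 with an intensity trend (44 higher and 80 lower with siRNA 1), 172 without the genes below the median gene mean (68 higher and 104 lower) and 9 without those below the 25th percentile (2 higher and 7 lower). Without siRNA 2 replicate 1 camera also called the fibroblast and feeder cell list (adjusted p = 0.0357).

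The time comparison set siRNA 1 at 96 h against siRNA 1 at 48 h. Naive pluripotency genes were lower at 96 h in 18 of 20 cases, higher in 1 and not passing in 1 (median -1.13, camera adjusted p = 3.9e-11, and adjusted p = 0.136 with an estimated correlation). Klf4 was lower by a log2 difference of -2.33 ± 0.079, Tbx3 by -1.87 ± 0.071, Esrrb by -1.68 ± 0.079, Nanog by -1.65 ± 0.096 and Tet2 by -1.34 ± 0.090. Lung genes differed between the times too, with a log2 median 1.79 higher over the 96 h arrays, as did the labelling, hybridisation and 18S control probe sets (log2 48 h minus 96 h of 0.704, -1.04 and 2.13). Targets of LIF and Stat3 were also lower, 12 of 21 against 4 higher and 5 not passing (median -0.42, camera adjusted p = 0.0027, and adjusted p = 0.136 with an estimated correlation), with Socs3 at -0.97 ± 0.075 and Gbx2 at -1.42 ± 0.089. The target list shares 5 genes with the naive list, Klf4, Tbx3 and Gbx2 among them, which were not taken out here. Epiblast genes were higher at 96 h in 12 of 19 cases and lower in 1 (median 0.78, camera adjusted p = 9.6e-06, and adjusted p = 0.136 with an estimated correlation), with Otx2 at 1.81 ± 0.073, Pou3f1 at 1.78 ± 0.088, Car4 at 1.68 ± 0.088 and Dnmt3b at 1.25 ± 0.071. Lefty1 was higher at 96 h by 1.19 ± 0.16. Adjusted over the list alone, 18 naive genes were lower and 1 higher, 14 targets were lower and 4 higher, and 12 epiblast genes were higher and 1 lower.

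Stress and metabolism lists differed between the times as well, beside the same differences in lung genes (1.79) and control probe sets (0.704, -1.04 and 2.13). Genes of the integrated stress and unfolded protein response were lower at 96 h in 12 of 20 cases and higher in 0 (13 and 0 adjusted over the list alone, median -0.51, camera adjusted p = 2.7e-06, and adjusted p = 0.160 with an estimated correlation). Examples were Xbp1 (-1.53 ± 0.071), Trib3 (-1.47 ± 0.080), the asparagine synthetase gene Asns (-1.29 ± 0.073) and Chac1 (-2.54 ± 0.15). Of 17 glycolysis and hypoxia genes 14 were lower and 1 higher (14 and 2 adjusted over the list alone, median -0.53, camera adjusted p = 9.6e-06, and adjusted p = 0.136 with an estimated correlation), among them Egln3, a prolyl hydroxylase induced by hypoxia (-2.57 ± 0.099), Pfkp (-2.08 ± 0.11) and Vegfa (-1.07 ± 0.094). Germline genes were lower in 9 of 19 cases and higher in 0 (10 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 0.0103, and adjusted p = 0.193 with an estimated correlation), with Sycp3 at -1.30 ± 0.093 and Sohlh2 at -1.62 ± 0.13. The p53 list was higher at 96 h (9 higher, 2 lower, median 0.28, camera adjusted p = 0.0072, and adjusted p = 0.136 with an estimated correlation), with 10 and 2 adjusted over the list alone and Plk2 at 1.11 ± 0.070. The extraembryonic endoderm list was higher (12 higher, 2 lower, the same adjusted over the list alone, median 0.27, camera adjusted p = 0.0090, and adjusted p = 0.204 with an estimated correlation), with Dab2 at 1.26 ± 0.12. Imprinted genes were higher (10 higher, 3 lower, 10 and 4 adjusted over the list alone, median 0.18, camera adjusted p = 0.0228, and adjusted p = 0.160 with an estimated correlation), with Peg3 at 1.77 ± 0.098 and Nnat at 1.82 ± 0.12. Cholesterol synthesis genes were higher (6 higher, 1 lower, the same adjusted over the list alone, median 0.20, camera adjusted p = 0.0211, and adjusted p = 0.469 with an estimated correlation), with Cyp51 at 0.71 ± 0.072, but this call was lost without siRNA 1 replicate 2 of 96 h (0.0510) or of 48 h (0.0586) and with quantile normalization (0.131). Without the genes below the median gene mean, the p53 (0.0972), extraembryonic endoderm (0.199), imprinted (0.260) and cholesterol (0.199) lists were not called.

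Over all genes, 5748 differed between the times, 2931 higher and 2817 lower at 96 h, and the count was 3664 without 48 h replicate 2. The largest rises at 96 h were in the lung genes Scgb1a1 (8.51 ± 0.25), Sftpc (4.80 ± 0.22), Bpifa1 (4.12 ± 0.24) and Cyp2f2 (3.13 ± 0.24), and in Rasef (3.16 ± 0.18), Calcr (3.07 ± 0.16), the ascorbate transporter gene Slc23a1 (2.98 ± 0.12) and the deubiquitinase gene Usp7 (2.95 ± 0.12). The largest falls were in H3c15 (-2.88 ± 0.083), Igsf21 (-2.82 ± 0.19), Emp1 (-2.61 ± 0.11), Egln3, Chac1, Ampd3 (-2.53 ± 0.11), Mymx (-2.50 ± 0.082) and the stress protein gene Nupr1 (-2.38 ± 0.16). At 48 h Scgb1a1 (mean 3.87), Bpifa1 (3.81) and Cyp2f2 (3.79) read near the trp control, a bacterial transcript taken as absent (mean 3.48 at 48 h), so they were not shown to be above background there. Their differences are lower bounds and their order is not known. Of the 21 lung genes 16 were higher by more than 1 on the log2 scale over the 6 arrays of 96 h than over the 48 h arrays, with a median of 1.79, whereas the medians of the other tissue lists lay between -0.22 and 0.062. The bacterial poly-A transcripts added as labelling controls read 0.704 higher on the 48 h arrays, the hybridisation controls 1.04 lower (log2 difference -1.04) and the probe sets for 18S ribosomal RNA 2.13 higher. Each control was read as the median over its probe sets on an array. Time and array handling cannot be told apart with these arrays.

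**Figure D4:**
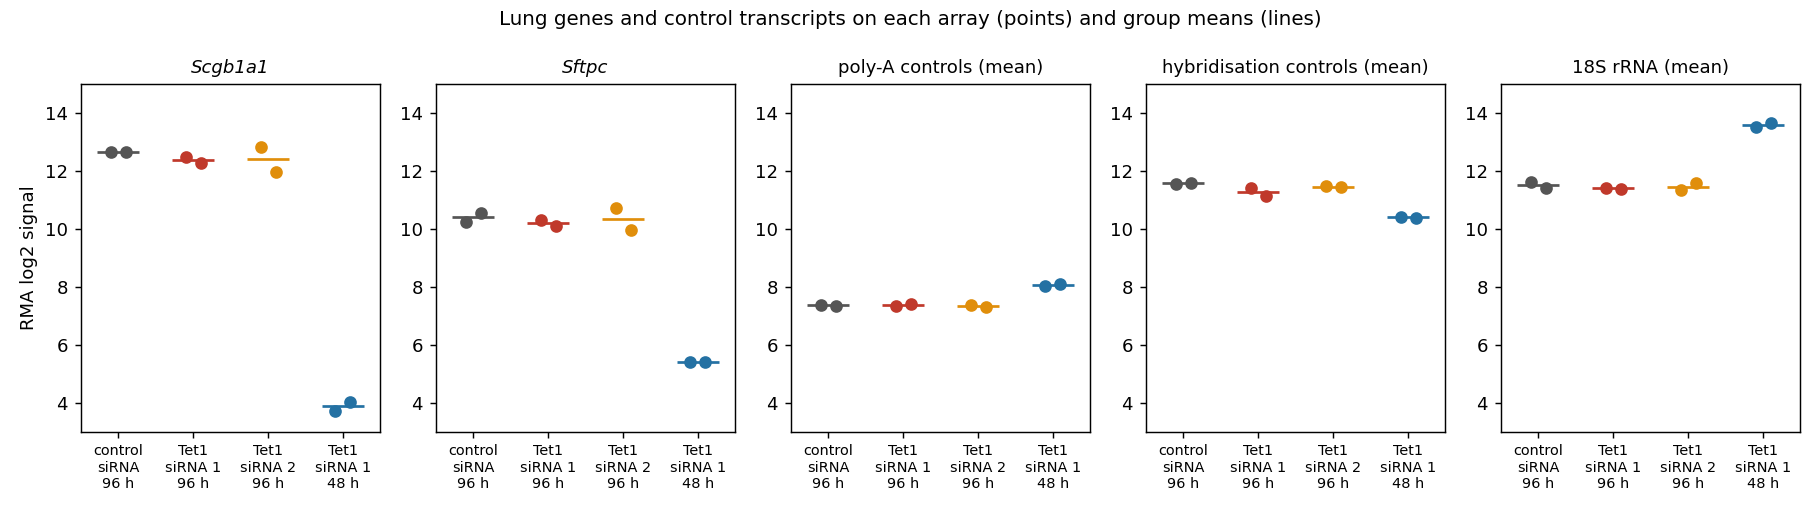
RMA log2 signal (vertical axis, the same for all panels) of the lung genes Scgb1a1 and Sftpc and the median signal over the poly-A control, hybridisation control and 18S rRNA probe sets on each array, grouped by siRNA and time (horizontal axis). The panel titles name this median a mean. Points are arrays and lines are group means, and the 48 h arrays stand apart from all 6 arrays of 96 h in each panel, with Scgb1a1 at a mean of 3.87 against 12.47.

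The earlier siRNA 1 arrays were also set against the control. No control at 48 h was analysed, so time and siRNA differ together, and the lung genes and control transcripts differ in the same way as above. Germline genes were higher at 48 h in 13 of 19 cases and lower in 0, or 13 and 1 adjusted over the list alone (median 1.02, camera adjusted p = 5.7e-07, and adjusted p = 0.202 with an estimated correlation). Mael rose by 2.12 ± 0.10, Ddx4 by 1.39 ± 0.067, Slc25a31 by 1.74 ± 0.13 and Taf7l by 1.55 ± 0.14. Targets of LIF and Stat3 were higher in 11 of 21 cases and lower in 2, the same adjusted over the list alone (median 0.30, camera adjusted p = 0.0170, and adjusted p = 0.253 with an estimated correlation), with Klf4 at 1.16 ± 0.079, Myc at 0.84 ± 0.080, Pim3 at 0.79 ± 0.082, Socs3 at 0.48 ± 0.075 and Egr1 at -0.81 ± 0.076. Klf4 is among the 5 targets shared with the naive list, which were not taken out here. The stress response list (14 higher, 2 lower, the same adjusted over the list alone, median 0.60, camera adjusted p = 0.00011, and adjusted p = 0.430 with an estimated correlation) held Xbp1 at 1.09 ± 0.071 and Asns at 1.07 ± 0.073, and the glycolysis and hypoxia list (10 higher, 2 lower, the same adjusted over the list alone, median 0.39, camera adjusted p = 0.00017, and adjusted p = 0.253 with an estimated correlation) held Egln1 at 1.25 ± 0.081 and Adm at 1.33 ± 0.12.

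The naive list was not called at 48 h (7 higher, 3 lower, 10 not passing, median 0.24, camera adjusted p = 0.243). Nanog was higher by 0.37 ± 0.096, Esrrb by 0.34 ± 0.079 and Tet2 by 0.54 ± 0.090, while Lefty1 was lower (-1.81 ± 0.16), as were Pax6 (-0.57 ± 0.090) and Tet3 (-0.53 ± 0.11). Pax6 and Tet3 were dim, with means of 4.68 and 5.07 at 48 h. The Nanog call was lost without control replicate 1 (adjusted p = 0.0583) or 2 (0.0730) and without 48 h replicate 1 (0.0583) or 2 (0.0977), and the Esrrb call without control replicate 1 or 48 h replicate 2 (0.0701 each). Over all genes, 5410 were called, 2605 higher and 2805 lower, and 3212 without 48 h replicate 2. The largest rises were in Egln3 (2.65 ± 0.099), Rnf128 (2.43 ± 0.071), the meiosis genes Tex11 (2.34 ± 0.21) and Stra8 (1.84 ± 0.15), Zc3h6 (2.24 ± 0.17), Mael, Cpe (1.797 ± 0.096) and Slc25a31. The largest falls were in the lung genes Scgb1a1 (-8.78 ± 0.25), Sftpc (-4.997 ± 0.22), Bpifa1 (-4.64 ± 0.24), Cyp2f2 (-3.07 ± 0.24), Lyz2 (-3.03 ± 0.20) and Cbr2 (-2.63 ± 0.27), and in Usp7 (-3.30 ± 0.12) and Spink1 (-2.73 ± 0.12). The falls of Scgb1a1, Bpifa1 and Cyp2f2 end near the absent trp control, as above, and are bounds on their size. Likewise Zc3h6 had a control mean of 3.74, where the trp control read 3.63 on both control arrays, so its rise is a lower bound.

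Across the 3 siRNA groups, 535 genes were called higher and 453 lower in all 3 comparisons with the control, and 253 were called in one direction with both siRNAs at 96 h and in the other at 48 h. Of these 253, 109 were lower at 96 h and higher at 48 h, among them Nanog, Klf4, Esrrb and Chac1. The other 144 were higher at 96 h and lower at 48 h, among them Calcr, Fndc3c1 and Tmem54. No control at 48 h was analysed, and lung genes and control probe sets differed between the times as above. In the 48 h comparison siRNA, time and array handling therefore cannot be told apart. Pair by pair, siRNA 1 at 96 h and at 48 h shared 777 genes called higher and 731 called lower, where independent lists would share 303.4 and 314.0, and 410 were called in opposite directions. For siRNA 2 at 96 h and siRNA 1 at 48 h it was 572 and 507, where independent lists would share 208.7 and 214.8, with 299 in opposite directions. How many opposite calls independent lists would share was not computed, for the 253 genes or for either pair. The counts of opposite calls were therefore not shown to exceed it. All 3 comparisons use the same control arrays. In 100 refits of simulated unchanged groups 0 calls were shared for either pair. With no changed genes in them, these refits cannot show how much shared controls add to such overlaps. The fold changes at 48 h correlated with those at 96 h with Pearson's r of 0.328 for siRNA 1 and 0.320 for siRNA 2, below the mean of 0.50 in simulated unchanged groups. The covariances were 0.0446 and 0.0361, above the highest simulated ones of 0.0065 for both pairs. Part of the excess in these overlaps may come from the shared controls.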

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

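The tests of the lung genes and of the labelling control transcripts were chosen only after their values had been seen, and the other tests were written before the values they measure. An SE given here for a list median comes from resampling its genes and does not measure the spread between arrays.

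The fold changes of siRNA 1 and siRNA 2 against the control moved together across genes, and shared control arrays are a technical source of such a relation. The covariance of the fold changes was 0.0886, and the highest of 1000 simulated covariances with shared controls and no other change was 0.0065. That argues against spread between single arrays in the shared controls as the whole source. The simulated spread was that between arrays of a group. A deviation common to both control arrays was not simulated and stays open. A common response to Tet1 depletion and a response to transfection with any duplex other than the control stay open. The level of Tet1 was not analysed here, so neither was tested.

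The siRNAs also differed from each other by a direct test, with 3 genes called, all lower with siRNA 1: Sult6b1 (log2 difference -1.06), Mymx (-0.97) and Serpinb6c (-0.88). The naive pluripotency list was lower with siRNA 1 (median -0.32), and the epiblast (0.11) and p53 (0.22) lists were higher, though with an estimated correlation none of these calls held (adjusted p = 0.153, 0.330 and 0.0964). An interferon response to one duplex was looked for in the interferon list, whose median difference was -0.0019 with an SE of 0.033. That argues against such a response in the listed genes at the size of the naive and p53 differences. Genes outside the list were not tested for it, and other responses to one duplex stay open. A stronger depletion of Tet1 by siRNA 1 may account for the difference, and 100% of the 3 genes were displaced further from the control with siRNA 1. That share rests on 3 genes, a duplex with more effects of its own would give it as well, and without the Tet1 level these cannot be told apart.

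The arrays of 48 h and 96 h differed by tests of the difference, with 253 genes called in one direction at 48 h and in the other with both siRNAs at 96 h, and with lower values at 96 h of Klf4 (-2.33), Nanog (-1.65), Esrrb (-1.68), Tet2 (-1.34) and Socs3 (-0.97). The count of 253 was not set against the number that independent lists would share. Lung RNA in the 96 h arrays may account for the lung genes, whose median was 1.79 higher at 96 h (SE 0.33) with Scgb1a1 at 12.47 against 3.87, while the lists of other tissues had medians between -0.22 and 0.062. At 96 h the lung genes differed between siRNA and control arrays by a median of -0.082 (SE 0.092). The 253 genes, which were selected as called, differed there by a median size of 0.54. The lung median is signed, so rises and falls of single lung genes cancel in it, whereas 0.54 is a median of sizes. The values argue only against a common shift of the lung genes of that size between siRNA and control arrays of 96 h. Single lung genes did differ, Napsa by -1.34 and Bpifa1 by -0.88. Napsa, however, read 6.99 to 7.77 on the siRNA arrays of 96 h and 7.16 and 7.12 on the 48 h arrays. Its siRNA arrays of 96 h thus lay near the 48 h arrays, unlike the median of the lung list. The calls at 48 h were made against control arrays that carry lung transcripts, and lung RNA stays open for them. Separate labelling or hybridisation of the 48 h arrays may add to the differences, because the poly-A control transcripts, which do not come from the cells, read 0.704 higher there. All arrays of 48 h share time and handling, so the part of each cannot be told apart, and a change with time after transfection stays open as a biological explanation that was not tested.

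Probe sets outside the gene tests also carried a signal: on the 48 h arrays the 18S ribosomal RNA probe sets read 2.13 higher than on the 96 h arrays. Of the 1222 probe sets without a gene symbol, 225 were called in the main comparison when all probe sets were tested.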

How the results depend on the processing

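The fits without the 48 h arrays, and with the lung genes as a covariate, were chosen after the data were seen. Of 300 called values of named genes, 267 stayed called in the same direction under each setting that gave them a value, and 0 turned. The adjusted p of 0.01 and the 1.5-fold minimum were applied to the counts of genes and not to single genes. Genes below a filter have no value under it, and fits without the 48 h arrays give none for the 48 h comparisons. Among values not called, Cdx2 in the main comparison turned to -0.065 without control replicate 2 (0.14 without control replicate 1, which set the range), and the imprinted list at 48 h turned with fry (adjusted p = 0.00054), which makes no comparison with other genes. The cause was not tested.

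At an adjusted p under 0.01 the counts were 1897 for both siRNAs, 1699 for siRNA 1, 941 for siRNA 2, 0 for siRNA 1 against siRNA 2, 3427 for 96 h against 48 h and 3068 for 48 h against control. With at least 1.5-fold change they were 875, 1137, 730, 1818 and 1591, the direct comparison of the siRNAs staying at 3. A stricter threshold gives fewer genes by construction. For siRNA 2 the count was 1364 with only the arrays compared and 1344 with the lung covariate. For siRNA 1 against siRNA 2 it was 124 with an intensity trend, 172 without genes below the median gene mean, 9 without those below the 25th percentile, and 0 with only the arrays compared, without the 48 h arrays, or with the lung covariate. The cause was not tested. No background values were used, so what signal over background limits was not tested.

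Leaving out 1 array gave 2218 to 3328 genes for both siRNAs, 1906 to 3348 for siRNA 1, 1160 to 2043 for siRNA 2, 0 to 3 for siRNA 1 against siRNA 2, 3664 to 5676 for 96 h against 48 h and 3212 to 5344 for 48 h against control, with the lone array of a group assumed to vary like the others. Fewer arrays lower the power. The covariance of the siRNAs ranged from 0.0859 to 0.0997. The lists called ranged from 7 to 8, 6 to 8, 7 to 8, 3 to 4, 9 to 10 and 4 to 4 in the same order. With the replicate number as a block the counts were 3403, 3256, 2096, 2, 5502 and 5165, the covariance was 0.0886, and the list counts stayed at 7, 7, 7, 3, 10 and 4.

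With an estimated correlation camera called 0 lists in each of the 6 comparisons. With fry it was 15 for both siRNAs, 14 for siRNA 1 and 11 for siRNA 2. It was 5 for siRNA 1 against siRNA 2, 13 for 96 h against 48 h and 11 for 48 h against control. For 96 h against 48 h, 6 lists were called without genes below the median gene mean. Without genes below the 25th percentile of the gene means, 1 list call was lost over all comparisons. Pseudocounts do not apply to log2 values, and robust eBayes for camera and a level of Tet1 were not run.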

Other observations

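The genes in this part were chosen after their values were seen. No control at 48 h was analysed, so in the 48 h values siRNA, time and array handling differ together. Of the 535 genes called higher than the control in all 3 siRNA groups, ranked by the smallest of the 3 changes, the first were Rnf128 (log2 2.60 with siRNA 1 and 2.37 with siRNA 2 at 96 h, 2.43 with siRNA 1 at 48 h), Pmaip1 (2.29, 1.71 and 1.70), Lrrc8c (1.59, 1.41 and 1.48), a subunit of volume-regulated anion channels, and Taf7l (1.51, 1.33 and 1.55). Casp8, the initiator caspase of death receptors, was higher by 1.95, 1.53 and 1.31, and Smo, the signal transducer of Hedgehog, by 1.13, 1.08 and 1.27. Of the 453 genes called lower in all 3 groups, Krt17 (-1.66, -1.56 and -2.38), Serpinb6c (-2.75, -1.88 and -1.41), the neuronal tubulin gene Tubb3 (-1.79, -1.26 and -1.32), Pdcl2 (-1.52, -1.26 and -2.12) and Trh, the precursor of thyrotropin-releasing hormone (-1.26, -1.27 and -2.44), came first. All 3 comparisons use the same control arrays.

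Lung transcripts also differed between the replicates of siRNA 2 at 96 h. Of 21 lung genes 20 were higher in replicate 1, with a median log2 difference of 0.72, against a median of -0.0080 over all genes. The lists of other tissues had median differences between the 96 h and 48 h arrays of -0.068 for liver, 0.055 for skeletal muscle and heart, 0.062 for brain, -0.059 for kidney, -0.22 for pancreas and gut and 0.041 for skin. The probe sets for beta-actin differed by -0.0075 and those for Gapdh by 0.17 between the 48 h and 96 h arrays.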
